A study of Mus musculus with 13 samples.

How the data were processed

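RNA from epididymal white fat of male mice was measured on 13 Affymetrix gene arrays in 4 groups. Per the labels, the groups were 3 wild type arrays after vehicle, 4 wild type arrays after α-galactosylceramide (αGalCer), 3 CD1d knockout arrays after vehicle and 3 CD1d knockout arrays after αGalCer. Per the labels' protocols, 100 ng of total RNA per array was labelled without removing ribosomal RNA, and samples needed an RNA integrity number above 8.0. The labels call the arrays of a group replicates and do not state how the RNA was divided between arrays. The p-values therefore measure the spread between these samples, which may in part be technical.

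The values are log2 expression values per probe set that the authors deposited, with 1 column per array. Per the submitters' processing notes they were made with RMA, which corrects the background, quantile normalises the probes and summarises them per probe set. The software version, the chip description file and the genome build are not given in the sources used here. The values ran from 1.53 to 13.84, and the array medians from 5.68 to 5.83. All 13 value columns were matched to samples by their labels. No detection calls were used here, so no probe set was declared absent. RMA compresses dim probe sets towards the background, so changes that start from a low level are understated. Scan dates are not given in the sources used here, so no scan batch was tested. The number of arrays limits the precision of every value.

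Probe sets were named from the platform annotation, and symbols were updated through Entrez identifiers with the RefSeq gene table of the assembly GRCm38.p6. That table served only for names, chromosomes and gene order, since no build is stated for the arrays. Of 35556 probe sets, 21218 had exactly 1 gene symbol, 1881 had several and 12457 had none. Among those with 1 symbol, 21185 matched through the Entrez identifier, 3 through an accession, and 30 kept the symbol of the annotation. Probe sets with several genes or none were named for no gene. For the 1388 genes with more than 1 probe set, the one with the highest mean over all arrays stood for the gene. This left 18818 genes, which were tested with no filter on dim genes.

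All 13 arrays entered 1 linear model in limma (version 3.58.1, R 4.3.3) with a mean per group and 9 residual degrees of freedom, and variances were moderated with eBayes and an intensity trend. It gave 5 contrasts: αGalCer minus vehicle in each genotype, the difference of these effects, and knockout minus wild type after each injection. Tests were two-sided. The p-values were adjusted over all genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Every adjusted p of a gene comes from this limma model, and ± after a change is its standard error (SE).

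The gene lists were written, like the model and the rule for naming genes, before the data were examined. There were 36 lists for cell types, macrophage states, cytokine responses, metabolism, stroma, tissues that dissection could add, and the region of the targeted gene. Lists share members; Chil3, for example, stands in the lists of alternatively activated macrophages, of the IL-4 axis and of monocytes. The 35 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, and p-values were adjusted over these lists within each contrast. Camera compares a list with all other genes. Fry asks whether the genes of a list move, on balance, in 1 direction and compares it with no other gene. A further 5 lists were added after the data were seen, leaving out the genes that had drawn attention, and their p-values are not adjusted.

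For each contrast the rule named the 8 called genes with the largest rise and the 8 with the largest fall whose groups did not overlap (for the difference of effects, called genes alone). RIKEN, Gm, LOC and predicted genes were skipped. From each list it named up to 4 members called in wild type, the 2 largest rises and the 2 largest falls, or the member with the smallest p where none was called. A further 26 genes of CD1d, IL-4 and macrophage biology were reported whatever their p. Other genes named in the text are members of the fixed lists, added as examples after their values were seen.

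The model was tested on simulated data made from the real means and spreads of all 18818 genes. For αGalCer in wild type it called 91% of genes changed by 1 on the log2 scale and 99% of those changed by 2, with 15 unchanged genes called. For αGalCer in knockout, with no gene changed, it called 0. For the difference of effects it called 95% of genes changed by 2. Camera called the 1 changed list and 0 random lists. The simulated genes were independent of each other, so this does not test camera where the genes of a list vary together.

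Alternatives covered the variance model, dim genes, normalisation, array weights, the arrays in the model, probe choice, unnamed probe sets, thresholds, the replicate number as a block and leaving out each array. After the data were seen, models without 3 arrays rich in epididymal or muscle transcripts, with a score of duct epithelium markers as a covariate, and without the genes that follow this score were added. Per-array list means were compared by exact permutation tests. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.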

Results

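Natural killer T (NKT) cells are lymphocytes that recognise lipids on CD1d, and αGalCer is a glycolipid that activates them when CD1d presents it. Mice without CD1d lack these cells. The study's title places NKT cell activation beside macrophage polarization in fat and IL-4 signalling through STAT6. Wild type and CD1d knockout males ate a high-fat diet for 4 days. They received αGalCer (100 ng per g of body weight) or the vehicle pyridine into the peritoneum on days 0 and 2, and the epididymal fat was taken on day 4 at 6.5 weeks of age. The first principal component of the 13 arrays held 70.3% of the variance. The 4 wild type arrays after αGalCer scored 66.9 to 80.2 on it and the other 9 arrays -44.4 to -20.7. Arrays correlated with those of their own group at 0.979 or more on average. The wild type arrays after αGalCer reached at most 0.966 with any array of another group. Each of the other 9 arrays correlated with some array of another group more than with its own group on average. By this measure only the wild type αGalCer group stood apart.

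Cd1d1, the targeted gene, lay at 10.69 ± 0.15 (SD, n = 3) in wild type fat after vehicle and at 3.73 ± 0.29 (SD, n = 3) in knockout fat. After αGalCer it lay at 9.63 ± 0.40 (SD, n = 4) and 3.15 ± 0.47 (SD, n = 3). All 6 knockout arrays were thus below all 7 wild type arrays. Cd1d2, which the name of the knockout strain lists beside it, lay at 4.84 and 4.76 after vehicle in wild type and knockout, so its probe set does not separate the genotypes. Cd1d1 fell by 1.06 ± 0.24 in wild type after αGalCer (adjusted p = 0.00288).

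The first comparison asked what αGalCer changes in fat that has NKT cells. Genes of macrophages, T cells, cytotoxic cells, interferon responses and cell division rose, and genes of adipocytes, fat synthesis and endothelium fell. The rise of Chil3, a chitinase-like protein of alternatively activated macrophages, reached 7.07 ± 0.35 on the log2 scale, a 134-fold difference (adjusted p = 4.09e-08). Gzmb, the cytotoxic protease granzyme B, rose 56.7-fold (5.82 ± 0.14). Pdcd1lg2, the ligand PD-L2, rose by 5.51 ± 0.15, the collagenase Mmp13 by 5.32 ± 0.22, the myeloid receptor Tarm1 by 5.14 ± 0.18, arginase (Arg1) by 5.14 ± 0.44, the ribonuclease Rnase2a by 5.01 ± 0.47 and the membrane protein Tm4sf19 by 4.67 ± 0.32. Nnat, an imprinted gene of adipocytes and neurons, had the largest fall, -4.07 ± 0.34, and the glutathione transferase Gstm7 (-3.92 ± 0.67), the methyltransferase Inmt (-3.58 ± 0.33) and the oxytocin receptor Oxtr (-3.42 ± 0.22) were among the next. In each of these genes all 4 arrays after αGalCer lay on 1 side of all 3 vehicle arrays. Of 18818 genes, 3733 rose and 4148 fell, or 41.9%, and 1392 and 1416 of these changed at least 2-fold. The groups did not overlap for 8782 genes, where chance gives 5.71% of genes. With a fold of at least 1.5 also required, 5019 genes remained called. Chil3 started from 4.02, the 18.5th percentile of genes, and it and Rnase2a belong to families of near-identical genes, so which member was measured is uncertain. Camera called 24 of 35 gene lists (15 higher and 9 lower), 2 of them with an estimated correlation, and fry called 29.

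Among 29 measured genes of alternatively activated (M2) macrophages, 25 rose and 1 fell over all genes tested, and 27 and 1 adjusted over the list alone. The list's median change was 2.30 (camera adjusted p = 7.21e-15, but adjusted p = 0.0691 with an estimated correlation). Besides Chil3 and Arg1, the lectins Mgl2 (2.30 ± 0.16), Clec10a (2.00 ± 0.21) and the mannose receptor Mrc1 (1.82 ± 0.21) rose. The scavenger receptor Cd163 rose by 0.82 ± 0.18, Il10 by 1.43 ± 0.19, and Retnla, which was already at 11.05 after vehicle, by 0.72 ± 0.12. The member that fell was Alox15, a lipoxygenase also found in eosinophils (-0.94 ± 0.30), a call that 7 alternatives lost and 11 kept. Of 25 genes of classically activated (M1) macrophages, 22 rose and 0 fell, with the same counts adjusted over the list alone. Their median was 2.05 (camera adjusted p = 6.94e-12, but adjusted p = 0.0691 with an estimated correlation). Ccl3 (4.23 ± 0.47), Cxcl10 (4.13 ± 0.20), the monocyte chemokine Ccl2 (3.94 ± 0.20), the integrin Itgax (3.14 ± 0.23), Tnf (2.78 ± 0.33) and nitric oxide synthase Nos2 (2.23 ± 0.28) rose. Il6 rose by 1.43 ± 0.34 from the low level of 2.61. Of 31 general macrophage genes 28 rose and 1 fell, with the same counts adjusted over the list alone and a median of 1.73. Their camera adjusted p was 3.97e-13, but adjusted p = 0.155 with an estimated correlation. The Fc receptor Fcgr1 (3.60 ± 0.23), the scavenger receptor Msr1 (3.35 ± 0.36) and Adgre1, which encodes F4/80 (1.39 ± 0.28), rose, and the lysozyme Lyz1 fell (-2.39 ± 0.19).

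**Figure D1:**
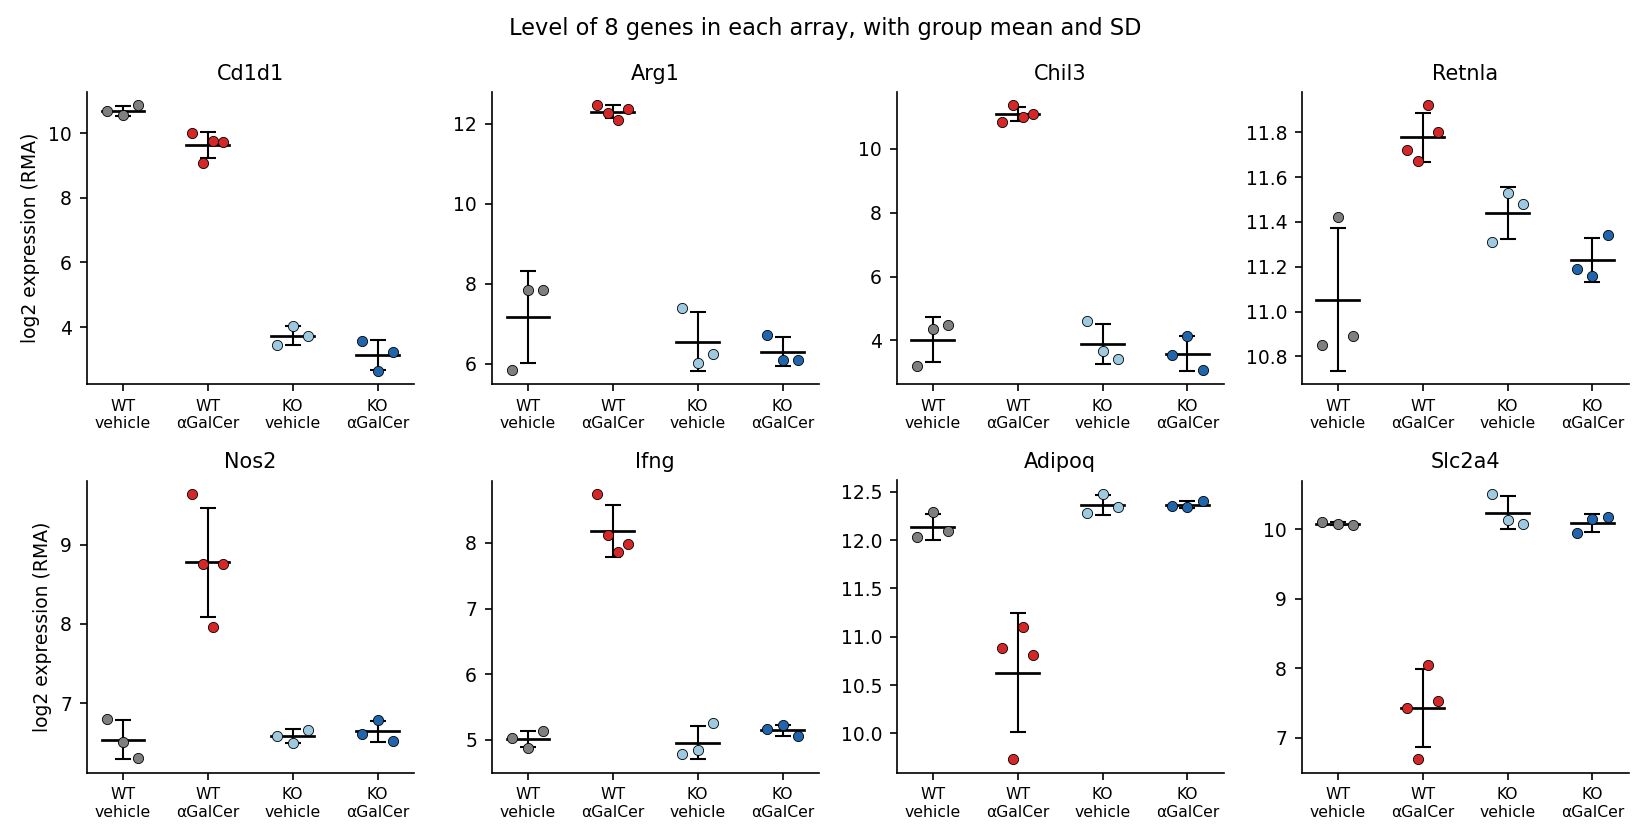
Level of 8 genes in each of the 13 arrays, as log2 RMA values (vertical axes differ between panels and do not start at 0), for wild type (WT) and CD1d knockout (KO) after vehicle or αGalCer; lines show the mean and bars 1 SD of 3 or 4 arrays. Arg1 lay at 12.30 in wild type after αGalCer and at 6.30 to 7.17 in the other group means, and Adipoq at 10.63 against 12.13 to 12.37.

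In the list for IL-4, IL-13 and STAT6, 20 of 24 genes rose and 2 fell, against 21 and 2 adjusted over the list alone, with a median of 0.95. The camera adjusted p was 1.31e-07, but adjusted p = 0.0691 with an estimated correlation. Il4 rose by 1.66 ± 0.15 from the low level of 3.77, and Il13 by 0.74 ± 0.22. The receptor chain Il4ra rose by 2.22 ± 0.22, and Stat6 by 0.18 ± 0.07 (adjusted p = 0.0444), a call that 10 alternatives lost and 7 kept. The members that fell were Pparg (-1.03 ± 0.10), the master regulator of adipocytes, called in all 18 alternatives, and Ppard (-0.31 ± 0.11), a call that 7 lost and 10 kept.

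All 21 measured T cell genes rose, also adjusted over the list alone, with a median of 1.86. Cd3g (3.59 ± 0.19) and Cd3e (3.23 ± 0.16), both of the T cell receptor complex, led them. Of 15 NKT cell genes 13 rose and 2 fell by both counts, over all genes and adjusted over the list alone, with a median of 2.21. Slamf6 (3.91 ± 0.11) and Il2rb (3.76 ± 0.23) rose most. These 2 lists kept their call with an estimated correlation (adjusted p = 0.0403 for each). The members that fell were Il17rb (-0.79 ± 0.27), a call that 6 alternatives lost and 11 kept, and Zbtb16, the transcription factor PLZF, by 1.76 ± 0.19 from 11.18, called in all 18. Zbtb16 was as high in knockout fat after vehicle (11.25), where NKT cells are absent. Of 20 genes of NK and cytotoxic cells, 20 rose, also adjusted over the list alone, with a median of 2.76 (camera adjusted p = 2.13e-15, but adjusted p = 0.103 with an estimated correlation). Granzyme A (Gzma) rose by 4.57 ± 0.18 and perforin (Prf1) by 4.10 ± 0.24.

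Monocyte genes numbered 13, of which 9 rose and 1 fell, against 10 and 1 adjusted over the list alone, with a median of 1.53. Besides Chil3, coagulation factor F10 rose (3.65 ± 0.29), and Ace, an enzyme also made by endothelium, fell (-1.59 ± 0.21). This list had adjusted p = 0.113 with an estimated correlation. Among 15 neutrophil genes 11 rose by both counts, over all genes and adjusted over the list alone, with a median of 1.55. The growth factor receptor Csf3r (3.08 ± 0.30) and the collagenase Mmp8 (2.98 ± 0.29) rose most, and the list had adjusted p = 0.221 with an estimated correlation. Dendritic cell genes rose in 13 of 19 cases and fell in 2 by both counts, over all genes and adjusted over the list alone, with a median of 1.05. The chemokines Ccl22 (3.35 ± 0.30) and Ccl17 (2.70 ± 0.42) rose, while Fscn1 (-0.65 ± 0.13) and Zbtb46 (-0.36 ± 0.12) fell, and the list had adjusted p = 0.149 with an estimated correlation. Camera called none of the eosinophil, mast cell and B cell lists (adjusted p = 0.476, 0.392 and 0.299). Of 10 eosinophil genes 3 rose and 2 fell, of 12 mast cell genes 1 rose and 3 fell, with the same counts adjusted over the list alone. Siglecf rose by 0.39 ± 0.11, histidine decarboxylase (Hdc) by 1.49 ± 0.33, and the stem cell factor receptor Kit fell by 0.95 ± 0.19. Of 18 B and plasma cell genes 5 rose, 2 of them adjusted over the list alone, led by Cd72 (1.93 ± 0.43) and Cd22 (1.67 ± 0.15).

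Interferon γ itself (Ifng) rose by 3.17 ± 0.19. Of 30 genes of its response and of antigen presentation 29 rose, also adjusted over the list alone, with a median of 2.27 (camera adjusted p = 1.18e-19, but adjusted p = 0.0691 with an estimated correlation). The Fc receptor Fcgr4 (4.44 ± 0.26) and the proteasome subunit Psmb8 (2.86 ± 0.17) were among them. Type I interferon genes rose in 21 of 26 cases, and 24 adjusted over the list alone, with a smaller median of 0.99 and adjusted p = 0.204 with an estimated correlation. Oas3 (2.69 ± 0.27) and Oasl1 (2.34 ± 0.17) led them. Of 40 chemokines and receptors 30 rose, also adjusted over the list alone, with a median of 1.90 and adjusted p = 0.0691 with an estimated correlation; Ccl8 rose by 4.63 ± 0.41. The acute phase list split, with 7 of 18 genes higher and 4 lower, or 8 and 4 adjusted over the list alone, and camera did not call it (adjusted p = 0.431). Timp1 (4.05 ± 0.42) and Socs3 (2.72 ± 0.36) rose, and Lbp (-1.38 ± 0.25) and Orm1 (-1.04 ± 0.19) fell. All 35 cell cycle genes rose, also adjusted over the list alone, with a median of 2.16 (camera adjusted p = 3.7e-22, but adjusted p = 0.103 with an estimated correlation). The mitotic kinases Bub1 (2.94 ± 0.37) and Plk1 (2.69 ± 0.20) led them, and the proliferation marker Mki67 rose by 2.16 ± 0.40. Of 16 immediate early genes 10 rose and 1 fell by both counts, over all genes and adjusted over the list alone. Atf3 (2.66 ± 0.23) and Fos (2.08 ± 0.27) rose, Dusp1 fell (-0.58 ± 0.11), and the list had adjusted p = 0.21 with an estimated correlation.

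All 27 measured adipocyte genes fell, also adjusted over the list alone, with a median of -1.33 (camera adjusted p = 7.21e-15, but adjusted p = 0.113 with an estimated correlation). Pck1, which makes the glycerol backbone of stored fat, fell by 3.04 ± 0.28, and the insulin-regulated glucose transporter Slc2a4 (GLUT4) by 2.65 ± 0.23. Leptin (Lep) fell by 1.83 ± 0.22 and adiponectin (Adipoq) went from 12.13 to 10.63 (SE of the change 0.24, adjusted p = 0.00019). Of 21 genes of fat synthesis 20 fell, also adjusted over the list alone, with a median of -1.51 and adjusted p = 0.113 with an estimated correlation. Thrsp (-3.30 ± 0.43), malic enzyme (Me1, -2.23 ± 0.24) and fatty acid synthase (Fasn, -1.81 ± 0.26) fell. Genes of insulin signalling and glucose uptake fell in 14 of 19 cases and rose in 3, against 16 and 3 adjusted over the list alone, with a median of -0.80 and adjusted p = 0.113 with an estimated correlation. Foxo1 fell by 1.60 ± 0.13, while the basal glucose transporter Slc2a1 (1.71 ± 0.26) and the phosphatase Ptpn1 (1.49 ± 0.11) rose. Thermogenic genes fell in 11 of 18 cases and rose in 1 by both counts, over all genes and adjusted over the list alone, with a median of -0.63 and adjusted p = 0.149 with an estimated correlation. The coactivator Ppargc1a fell by 1.98 ± 0.19, the beige fat marker Tmem26 rose by 3.52 ± 0.15, and Ucp1 changed by 0.37 ± 0.18 (adjusted p = 0.112). Slc27a2 of this list fell by 2.19 ± 0.51 and had a similar value in knockout (-2.14 ± 0.54, adjusted p = 0.72). Oxidative phosphorylation and citrate cycle genes fell in 16 of 28 cases and rose in 1, against 19 and 1 adjusted over the list alone. The median of -0.30 was small, and the list had adjusted p = 0.288 with an estimated correlation. Idh3a fell by 1.56 ± 0.10, and Cox5a rose by 0.36 ± 0.10.

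Each of 21 endothelial genes fell, also adjusted over the list alone, with a median of -1.52 (camera adjusted p = 3.39e-14, but adjusted p = 0.0841 with an estimated correlation). The lymphatic gene Mmrn1 fell by 2.72 ± 0.31 and the VEGF receptor Kdr by 2.57 ± 0.10. Of 20 fibroblast and preadipocyte genes 14 fell and 1 rose, against 15 and 1 adjusted over the list alone, with a median of -0.83 and adjusted p = 0.221 with an estimated correlation. Igfbp6 (-1.42 ± 0.15) and Ccn3 (-1.28 ± 0.24) fell, and Thy1, which T cells also express, rose (0.98 ± 0.14). Extracellular matrix genes went both ways, 9 of 34 up and 15 down, or 10 and 15 adjusted over the list alone, and camera did not call the list (adjusted p = 0.482). The elastase Mmp12 rose by 4.14 ± 0.14, lumican (Lum) fell by 2.04 ± 0.24, and Col1a1 changed by 0.03 ± 0.13 (adjusted p = 0.905). Mesothelial genes fell in 6 of 12 cases, and 7 adjusted over the list alone, with a median of -0.93 and adjusted p = 0.243 with an estimated correlation; Igfbp5 (-2.09 ± 0.13) and Rspo1 (-1.61 ± 0.25) fell.

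Of 16 clock genes 3 rose and 10 fell by both counts, over all genes and adjusted over the list alone, with a median of -1.12 (camera adjusted p = 0.00135, but adjusted p = 0.0691 with an estimated correlation). Arntl, which encodes BMAL1, rose by 1.43 ± 0.20 and the repressor Nfil3 by 2.04 ± 0.21, while Per3 (-2.33 ± 0.14) and Hlf (-1.99 ± 0.14) fell. Glucocorticoid response genes rose in 2 of 16 cases and fell in 7, against 4 and 9 adjusted over the list alone, and camera did not call the list (adjusted p = 0.0644). Cdkn1a rose by 1.53 ± 0.20, Mt2 rose by 0.39 ± 0.10 and Ddit4 fell by 1.65 ± 0.11.

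**Figure D2:**
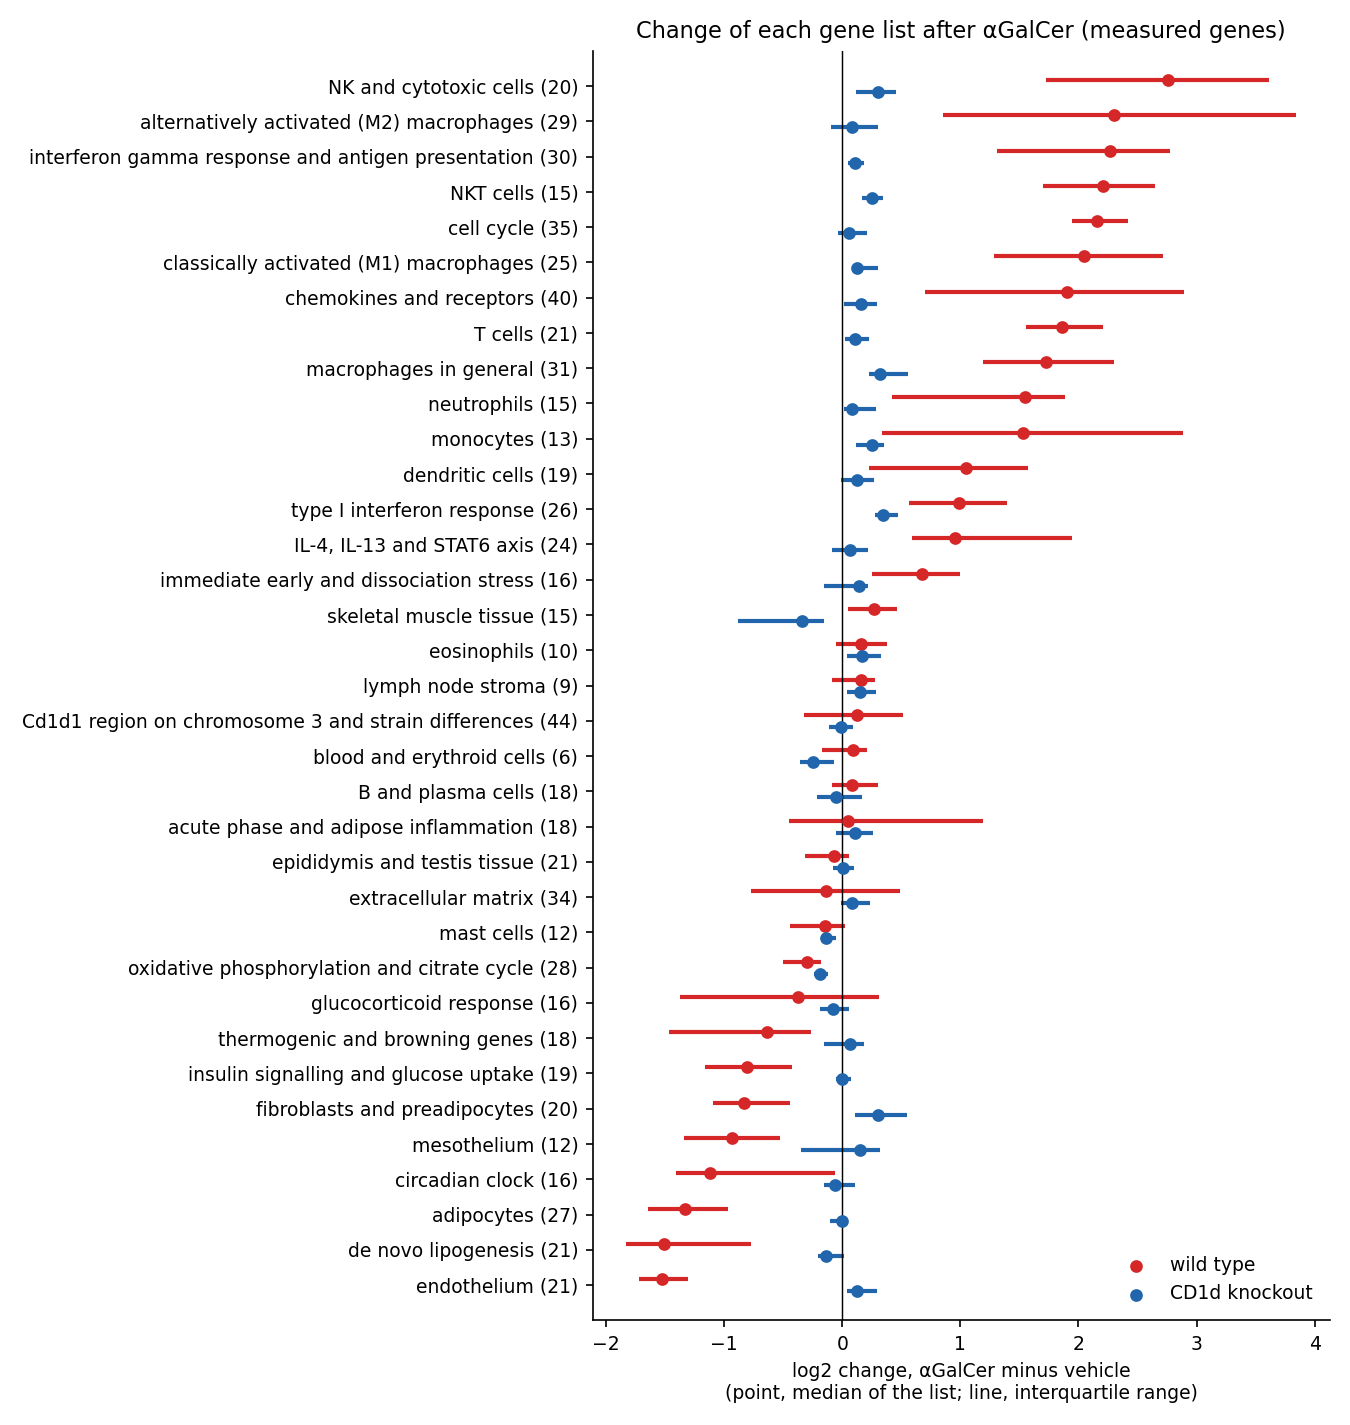
Median log2 change after αGalCer (points) and interquartile range over the members (lines) of 35 gene lists in wild type and CD1d knockout; numbers in brackets are measured genes. Wild type medians run from -1.52 for endothelium to 2.76 for NK and cytotoxic cells, and knockout medians from -0.34 for muscle to 0.35 for type I interferon genes.

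Among the lists for tissue that dissection could add, camera called the mesothelial list lower in wild type, though not with an estimated correlation. The lists for epididymis and testis, muscle, lymph node and blood were not called in wild type. Of 21 genes of epididymis and testis 1 fell, of 15 muscle genes 1 fell, of 9 lymph node genes 1 rose and of 6 blood genes 1 rose. Adjusted over the list alone these counts were 0, 0, 1 and 1, and the camera adjusted p was 0.56, 0.808, 0.481 and 0.785. The called members were Lcn8 (-0.35 ± 0.10), Myl1 (-1.33 ± 0.38), lymphotoxin β (Ltb, 1.27 ± 0.15), which lymphocytes make, and Slc4a1 (1.24 ± 0.37). Single arrays stood apart. The epididymis list averaged 4.62 in wild type vehicle replicate 3 and 3.66 to 3.98 in the other arrays. The muscle list averaged 8.18 in knockout vehicle replicate 1, 6.64 in replicate 2 and 8.46 in knockout αGalCer replicate 3, against 5.01 to 5.81 elsewhere. Transcripts of ciliated and ductal epithelium varied between the vehicle arrays. A score of 50 such markers, listed after the data were seen, ran from -0.32 to 1.64 in the 6 vehicle arrays. In the 7 αGalCer arrays it ran from -0.51 to -0.39. The exact permutation test, two-sided, gave p = 0.000583, with 0.0286 for wild type alone and 0.1 for knockout alone. Each is the smallest that its splits can give (1716, 35 and 20). The markers were listed after these arrays were seen, so these p-values are no independent support. Mmp7, a protease of ductal epithelium, had a change of -3.87 ± 0.80 in wild type and of -3.28 ± 0.85 in knockout. Dcdc2a (-3.48 ± 0.69), Dao (-3.48 ± 0.87) and Cuzd1 (-3.45 ± 1.02) also fell in wild type and had values of -2.94, -3.11 and -2.02 in knockout. Across the 6 vehicle arrays 1936 genes followed this score (r of at least 0.8), where chance gives about 527. In wild type 968 of them were called, a share of 50% against 41.9% of all genes.

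**Figure D3:**
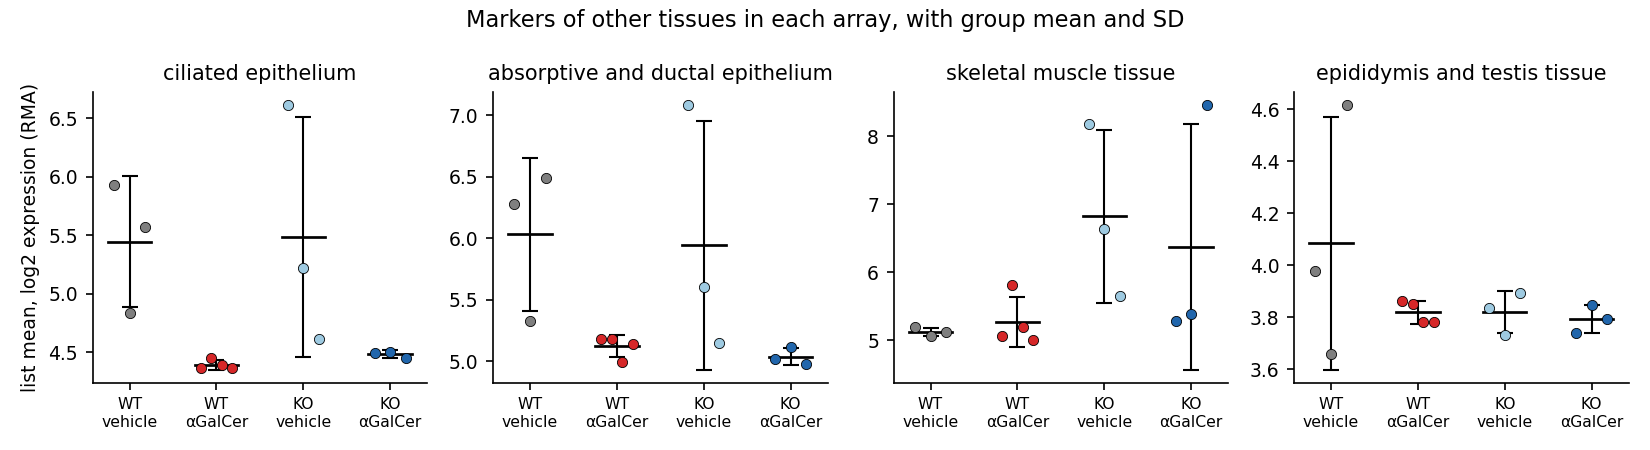
Mean log2 RMA value of 4 lists of other tissues in each array (axes differ and do not start at 0), with the mean and SD of each group. Ciliated and ductal markers are highest in knockout vehicle replicate 1 (6.61 and 7.08), muscle markers in knockout αGalCer replicate 3 (8.46), and epididymal markers in wild type vehicle replicate 3 (4.62).

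The knockout comparison asked what αGalCer does where its presenting molecule is missing. No gene was called by limma in either direction. At an unadjusted p under 0.05 there were 1281 genes, where chance gives 941, and the smallest adjusted p was 0.599. The groups did not overlap for 2603 genes, where chance gives 10% of genes. Arg1 changed by -0.25 ± 0.47, Chil3 by -0.31 ± 0.37, Gzmb by 0.11 ± 0.15, Ifng by 0.19 ± 0.20 and Adipoq by 0.00 ± 0.25. Rnase2a, which rose in wild type, had -2.58 ± 0.50 (adjusted p = 0.72). Camera called 11 lists higher and 2 lower, but 0 with an estimated correlation and 0 by fry. Macrophage genes had a median of 0.32 (camera adjusted p = 4.71e-09, but adjusted p = 0.576 with an estimated correlation), with Gpnmb at 1.23 ± 0.43. Type I interferon genes had a median of 0.35 (camera adjusted p = 3.11e-07, but adjusted p = 0.576 with an estimated correlation), and fibroblast genes 0.30 (1.6e-05, but adjusted p = 0.39 with an estimated correlation). Oxidative phosphorylation genes had -0.19 (8.09e-10, but adjusted p = 0.39 with an estimated correlation). With limma's array weights, which gave knockout vehicle replicate 2 a weight of 5 and replicate 1 a weight of 0.2, 322 genes were called. Without knockout vehicle replicate 3, 2 genes were called.

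The difference of the αGalCer effects, wild type minus knockout, tested the dependence on CD1d directly. Rnase2a (7.59 ± 0.68), Chil3 (7.38 ± 0.51), Gzmb (5.72 ± 0.21), Pdcd1lg2 (5.41 ± 0.22), Tarm1 (5.40 ± 0.27), Arg1 (5.39 ± 0.65), Mmp13 (5.25 ± 0.32) and Ccl8 (5.00 ± 0.60) differed most upwards. Nnat (-4.19 ± 0.50), Pck1 (-3.47 ± 0.42), the monooxygenase Fmo2 (-3.37 ± 0.32), Btnl9 (-3.36 ± 0.25), the prostaglandin receptor Ptger3 (-3.29 ± 0.43), Negr1 (-3.28 ± 0.37), Depp1 (-3.24 ± 0.25) and the transporter Slc6a13 (-3.17 ± 0.39) differed most downwards. Il4 (1.43 ± 0.22), Il4ra (2.21 ± 0.32), Mrc1 (1.51 ± 0.31), Retnla (0.94 ± 0.18), Nos2 (2.18 ± 0.41) and Ifng (2.98 ± 0.28) also differed, with adjusted p between 1.3e-05 and 0.00227. The difference was not called for Il13 (0.88 ± 0.33, adjusted p = 0.0625), Stat6 (0.10 ± 0.10, adjusted p = 0.526), Il6 (1.41 ± 0.51, adjusted p = 0.0552), Cd163 (0.58 ± 0.26, adjusted p = 0.125) and Adgre1 (0.87 ± 0.41, adjusted p = 0.143). Nor was it for Mmp7 (adjusted p = 0.79), Dao (0.885), Dcdc2a (0.772), Cuzd1 (0.564) and Gstm7 (0.183), all of which fell in wild type. In total 2611 genes had a higher and 2698 a lower change in wild type. Camera called 15 lists higher and 9 lower, of which 2 held with an estimated correlation.

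Across genes the log2 changes of the genotypes, which share no array, correlated at r = 0.335 (Spearman 0.202) over 18818 genes; genes are not independent replicates. Over the 7881 genes called in wild type r was 0.381 with a slope of 0.106, and the median size of change was 0.75 in wild type and 0.12 in knockout. The share of these genes with the same sign was 58.6%. Without the genes that follow the duct epithelium score r was 0.218.

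**Figure D4:**
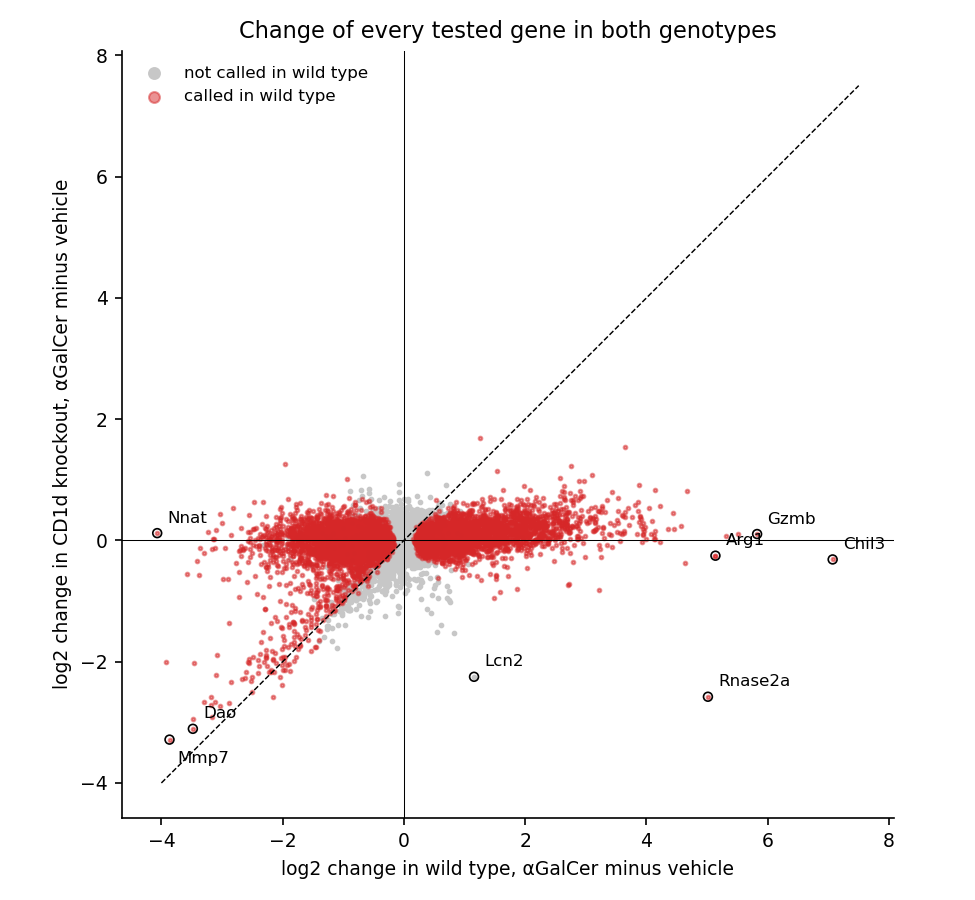
Log2 change after αGalCer of each tested gene in wild type (horizontal) and CD1d knockout (vertical), with genes called in wild type in red; the dashed line marks equal changes. Chil3, Gzmb, Arg1 and Nnat lie near 0 on the knockout axis, Mmp7 and Dao near the line of equal changes, and Rnase2a at 5.01 in wild type and -2.58 in knockout.

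The genotypes were next compared after vehicle. Besides Cd1d1, lower by 6.96 ± 0.26 (-6.96, adjusted p = 3.35e-08), the knockout had less Mogat2, a monoacylglycerol acyltransferase (-2.30 ± 0.23, adjusted p = 0.00134), less of the glutamate receptor Gria4 (-0.81 ± 0.13) and less of the complement protease Masp1 (-0.76 ± 0.11). It had more of the serine protease inhibitor Serpina3b (2.15 ± 0.26, adjusted p = 0.00536), the calcium sensor Hpca (1.85 ± 0.27), the kinase Dclk2 (1.43 ± 0.12, adjusted p = 0.000396), the secretin receptor Sctr (1.26 ± 0.17), Srpx (1.24 ± 0.17), Mir365-2 (1.16 ± 0.18), complement C2 (1.12 ± 0.18) and the phospholipase Pla2g2d (1.05 ± 0.14). In all 17 genes were higher and 4 lower. The groups did not overlap for 2104 genes, where chance gives 10% of genes. Arg1 (-0.62), Il4 (-0.04), Ifng (-0.06), Adipoq (0.23) and Lep (0.20) were not called, with adjusted p of 0.864 or more. Dclk2 is 2 tested genes from Cd1d1 on chromosome 3, and Gatb (0.76 ± 0.10), also higher, is 12 away in the gene order of GRCm38.p6. Of 44 genes in the list for the Cd1d1 region, 2 were higher, and 3 higher and 2 lower adjusted over the list alone; this list was not called by camera (adjusted p = 0.84), nor was it after αGalCer in wild type (14 rose and 11 fell, or 16 and 11 adjusted over the list alone, adjusted p = 0.275).

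B and plasma cell genes were higher in the knockout after vehicle, with a median of 0.32 over 18 genes (camera adjusted p = 8.85e-06 and adjusted p = 0.0161 with an estimated correlation). No member was called over all genes and 1 was adjusted over the list alone; Cd79a, a chain of the B cell receptor, differed by 0.62 ± 0.15 (adjusted p = 0.255). After αGalCer the list did not differ as a set (median 0.16, camera adjusted p = 0.784), with 4 genes higher and 3 lower in the knockout, or 4 and 4 adjusted over the list alone. After vehicle camera called 7 lists higher and 5 lower in the knockout, and only the B cell list with an estimated correlation. The blood list was among those higher (median 0.28 over 6 genes, camera adjusted p = 0.00349, but adjusted p = 0.439 with an estimated correlation), with array means of 6.81 to 6.89 in knockout and 6.09 to 6.49 in wild type. B cells in the fat were thus not separated from blood in the tissue. Muscle genes had a median of 1.68 after vehicle (camera adjusted p = 8.85e-06, but adjusted p = 0.767 with an estimated correlation), with the muscle list high in knockout vehicle replicates 1 and 2. The count of 21 genes moved with single arrays and settings. It was 11 without wild type vehicle replicate 3, 12 without the 3 arrays rich in epididymal or muscle transcripts, 4 with only these groups in the model, and 169 with array weights.

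**Figure D5:**
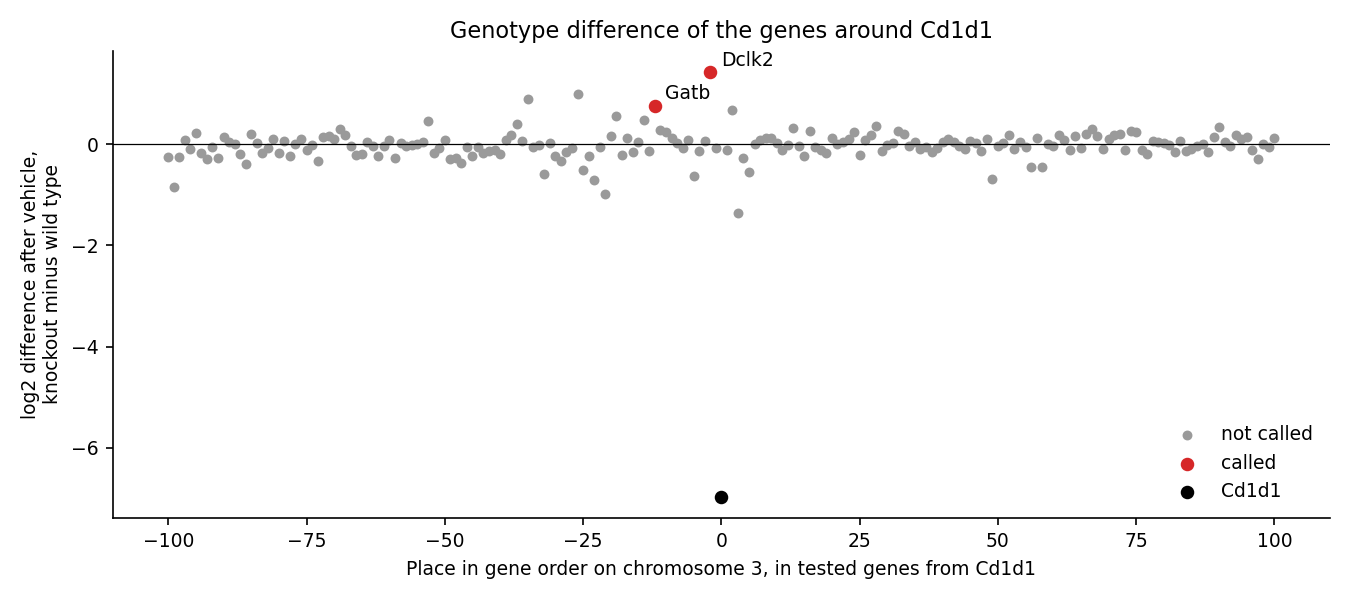
Log2 difference between knockout and wild type after vehicle (vertical) for the 100 tested genes on either side of Cd1d1, by their place in gene order on chromosome 3 (horizontal). Cd1d1 lies at -6.96, and the called neighbours Dclk2 and Gatb at 1.43 and 0.76.

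After αGalCer the genotypes differed widely. Knockout fat had less Chil3 (-7.51 ± 0.35), Cd1d1 (-6.49 ± 0.24), Rnase2a (-6.40 ± 0.47), Arg1 (-6.01 ± 0.44), Pdcd1lg2 (-5.33 ± 0.15), Gzmb (-5.28 ± 0.14), Mmp13 (-5.28 ± 0.22) and Tarm1 (-5.12 ± 0.18) than wild type fat. It had more Nnat (4.63 ± 0.34), Inmt (4.38 ± 0.33), Oxtr (3.62 ± 0.22), Thrsp (3.54 ± 0.43), the cytochrome Cyp2e1 (3.52 ± 0.37), Serpina3b (3.45 ± 0.24), the imprinted gene Peg3 (3.40 ± 0.20) and butyrylcholinesterase (Bche, 3.39 ± 0.32). There were 4121 genes higher and 3618 lower in the knockout, and 4888 in all with a fold of at least 1.5. The groups did not overlap for 9477 genes, where chance gives 5.71% of genes. All 27 adipocyte and 21 endothelial genes were higher, also adjusted over the list alone, with adjusted p = 0.126 and 0.097 with an estimated correlation. The 21 T cell genes were all lower, also adjusted over the list alone (adjusted p = 0.0438 with an estimated correlation). Of the 21 genes that differed after vehicle, 17 were called here as well and 16 of those in the same direction, where 41.1% of all genes were called. Some of the 21 genes were also changed by αGalCer in wild type, so a call here need not repeat the difference after vehicle. Mogat2, Gria4 and Hpca were not called (0.00, 0.30 and 0.21), and neither was the protease Prtn3 (-0.23, against 1.00 after vehicle). The complement protease Masp1 was lower after vehicle and higher after αGalCer (0.65, adjusted p = 0.000188), having fallen by 1.44 in wild type.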

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

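The comparison of the endothelial with the fibroblast list, that of the fat synthesis with the adipocyte list, the test of genes near Cd1d1, the exchange of genotype labels, the comparison with genes of like level, the slope on the muscle list and the models of the epithelial ratio without 1 array were chosen after the results were seen, as were the epithelial lists and the models without 3 arrays.

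The effect of αGalCer differed between wild type and knockout for 5309 genes by the test of the difference itself. Of the 26 genes followed whatever their p, 18 differed. Upwards in wild type relative to knockout were Chil3 (7.38), Arg1 (5.39), Ccl2 (3.84), Itgax (2.98), Ifng (2.98), Mgl2 (2.40), Tnf (2.38), Il4ra (2.21), Nos2 (2.18), Clec10a (1.87), Mrc1 (1.51), Il4 (1.43), Il10 (1.11) and Retnla (0.94) on the log2 scale. Downwards were Slc2a4 (-2.5), Lep (-1.86), Zbtb16 (-1.68) and Adipoq (-1.5).

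Only the 4 wild type arrays after αGalCer form a group large enough to look for a single array far from the others. Of 62 gene levels and list means, 3 had one, and chance gives about 1 in 20. The gap of the outlying array over the group's range was 0.874 for Mrc1 (replicate 1 at 11.09, the others higher), 0.939 for the mean of the fat synthesis list (replicate 2 at 9.11, the others higher) and 0.868 for that of the B and plasma cell list (replicate 4 at 5.37, the others higher). Among probe sets that belong to no single gene, which the comparisons by gene leave out, 2991 were called in wild type after αGalCer and 0 by limma in knockout.

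Other splits of the arrays were counted for each comparison. For αGalCer in wild type, 1 of 35 splits, the real one, gave as many genes as its 7881, and the highest other gave 3844. A share of 1 in 35 is the smallest that these splits can give, so chance is unlikely but not excluded. For the genotypes after αGalCer, 1 of 35 splits gave as many as the real 7739, and the highest other gave 4031. Chance is again unlikely but not excluded. For the difference of effects, 2 of 100 drawn treatment splits gave as many as the real 5309. The other, with 6210, kept the wild type groups and exchanged the 2 knockout groups as a whole, so it counts the sum of the 2 effects and not a mixture of arrays. Splits that break up the wild type groups remove the wild type effect by design, so these splits decide nothing. Genotype labels were therefore exchanged within each injection, and 3 of 100 drawn splits gave as many genes as the real one. The 2 others, with up to 6000, kept the αGalCer arrays in their real groups and exchanged vehicle arrays. The highest of the remaining splits gave 788. Those splits break up the αGalCer groups and so remove their difference by design. This exchange therefore decides nothing about the difference of effects either. For αGalCer in knockout the 10 splits are too few for a share under 0.05; all 10 gave at least the real 0, and the highest other gave 6. For the genotypes after vehicle the 10 splits are also too few; 2 gave at least the real 21, and the highest other gave 507. That split joins wild type replicates 1 and 3 with knockout replicate 1, the 3 arrays with the highest duct epithelium score, which points to a structure of the vehicle arrays other than genotype.

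Genes of ciliated and ductal epithelium had negative medians after αGalCer in both genotypes; the most abundant, Spint2, Lrp2 and Cfap126, lay at 8.28, 8.25 and 7.07 in wild type after vehicle. Of 25 ciliated genes 13 fell in wild type (median -1.02, camera p = 0.00155, and p = 0.451 with an estimated correlation), against 0 called by limma in knockout (median -0.86, camera p = 7.79e-17, but p = 0.0677 with an estimated correlation). Of 25 ductal genes 10 fell in wild type (median -0.84, camera p = 0.0104, and p = 0.507 with an estimated correlation), against 0 in knockout (median -0.95, camera p = 7.31e-12, but p = 0.0977 with an estimated correlation, and exact permutation p = 0.1 for the score of both lists). The ratio of the knockout to the wild type median was 0.84 for the ciliated list but 0.28 without knockout vehicle replicate 1 (0.70 to 1.26 without any other array), so a response that needs CD1d stays open. Across the 6 vehicle arrays the list means rose and fell together (r = 0.961, exact permutation p = 0.00417). Both lists were written after these arrays were seen, so neither this p nor the other p-values of these lists give independent support. Duct tissue left on some fat pads at dissection would give such a pattern and may be the source. An effect of αGalCer on such tissue, with or without CD1d, stays open, since all 7 αGalCer arrays were low.

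Adipocyte, endothelial and most fibroblast genes fell in wild type after αGalCer, while immune cell genes rose. RNA of incoming immune cells would dilute all of them by the same amount only if those cells express none of them. The endothelial list fell by 0.925 more than the fibroblast list (-0.925, exact permutation p = 0.0286, the smallest that 35 splits can give). This argues against an equal dilution of both lists. The fibroblast list holds Thy1, which T cells also express and which rose, but this is 1 of its 20 measured genes. Whether incoming cells express other members was not tested, so unequal falls do not decide on dilution as the whole cause. A rescaling by RMA would move genes of like level alike, but the 68 genes of the 3 lists changed by a mean of -1.17 relative to the median of the 500 genes nearest to each in level (exact permutation p = 0.0286), which argues against it; the median over all genes, -0.018, is held near 0 by quantile normalisation and decides nothing by itself. The fat synthesis list fell as far as the adipocyte list (difference -0.004, exact permutation p = 1), which argues against a fall of fat synthesis beyond that of other adipocyte genes. Dilution in part or in whole, a loss or repression of endothelial genes, and a change in total RNA, which normalised arrays cannot show, stay open.

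Of the genes that differed between genotypes after vehicle, Dclk2 and Gatb lie near Cd1d1. Both belong to a list of 44 genes of this region and of strain differences fixed before the data were seen, of which 2 were called against 18 of 18773 others (odds ratio 49.5, 95% interval 5.41 to 219, Fisher's exact p = 0.000988; 10.4 for the 200 nearest tested genes, a window set after these calls were seen), while camera, which looks for a shift in 1 direction, did not call the list (adjusted p = 0.84). Without the 3 arrays rich in epididymal or muscle transcripts, the epididymal list's difference went from -0.27 to -0.01. Of the 21 genes, 100% then kept more of their change than they lost, and 8 stayed called. The 21 genes were called on these same arrays, which favours genes of small spread, so this outcome was largely set by the call. It says only that the arrays left out do not give most of each difference. Muscle tissue, which knockout vehicle replicate 2 still held, was examined by the slope on the muscle list within the knockout groups. That slope gives a median of 4.03% of the difference of the 21 genes (-5.84% to 15.9%). It gives 91.8% for the 15 muscle genes, but these make up the list, so a high share was set in advance. Small slopes of the 21 genes were again largely set by the call. They say only that the level of the muscle list gives little of the difference of these 21 genes. The name of the knockout strain gives a donor strain besides C57BL/6, so donor DNA carried along with the allele may explain both neighbours, but 2 genes do not show it, and it stays open. An effect of the lost Cd1d1 on its neighbours was not tested and stays open too.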

How the results depend on the processing

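The models without 3 arrays, with the duct epithelium score as a covariate, and without the genes that follow it were chosen after the data were seen. For αGalCer in wild type the count of 7881 stayed within 1.5-fold in every other model run except with a fold of at least 1.5 as well (5019), a stricter rule; leaving out 1 array gave 6753 to 7514. For the genotypes after αGalCer that rule gave 4888 in place of 7739, and leaving out 1 array gave 6674 to 7459. The difference of effects, 5309 genes, kept within 1.5-fold throughout, with 4531 to 5597 when 1 array was left out.

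For αGalCer in knockout the count was 0 in all models but 2. Array weights gave 322 genes, of which 210 were called in wild type, 154 in the same direction. Leaving out 1 array gave 0 to 2, the 2 without knockout vehicle replicate 3. The cause was not tested.

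For the genotypes after vehicle, 21 genes were called. The count was 169 with array weights and 42 with the duct epithelium score as a covariate, and both held all 21. It was 12 without the 3 arrays rich in epididymal or muscle transcripts (8 shared), with fewer arrays, and 4 with only the groups compared in the model (3 shared), with fewer residual degrees of freedom. At an adjusted p under 0.01 it was 9, a stricter rule. Leaving out 1 array gave 11 to 19, the 11 without wild type vehicle replicate 3. The cause of the rises was not tested.

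Of the gene lists, camera called 24 in wild type, 2 with an estimated correlation, and 24 to 25 when 1 array was left out. The correlation of αGalCer effects between genotypes, 0.335, was 0.276 without the dimmest 40% of genes, 0.381 over genes called in wild type and 0.218 without the genes that follow the duct epithelium score, with 0.262 to 0.397 when 1 array was left out.

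With the replicate number as a replicate block, the counts were 7766 and 0 for αGalCer in wild type and knockout, 5461 for their difference, 17 and 7637 for the genotypes after vehicle and αGalCer, and 24 lists. Of 18 correlations between arrays of equal number in different groups, 5 were over 0.1, and the 18 ran from -0.203 to 0.484. Between the vehicle groups they were 0.481, 0.484 and -0.113 for replicates 1, 2 and 3. Arrays of unequal number were not compared, so these values do not settle whether the replicate numbers pair the arrays.

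Of 3010 comparisons of a named gene with an alternative, 2918 kept their direction and side of the threshold, 89 lost the call, 3 gained one and 0 reversed. In wild type Stat6 lost its call in 10 and kept it in 7, Alox15 in 7 and 11, Ppard in 7 and 10, Il17rb in 6 and 11 and Zbtb46 in 5 and 13. For the genotypes after vehicle, C2 lost its call in 7 and kept it in 10, Gria4 in 7 and 9, Mir365-2 in 6 and 11 and Masp1 in 5 and 12, while Cd1d1, Mogat2, Serpina3b and Dclk2 kept theirs in all 17. Of 451 for lists in wild type, 422 kept theirs, 22 lost the call, 7 gained one and 0 reversed. Signal over background limits dim genes, whose changes are understated.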

Other observations

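The lists of imprinted genes, co-inhibitory receptors and osteoclast genes were written, and all 3 tests chosen, after the data were seen; the genes that had drawn attention were left out, and no p below is adjusted.

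Co-inhibitory receptors, which restrain lymphocytes and myeloid cells, rose in wild type after αGalCer: 12 of 12 genes, also adjusted over the list alone, with a median of 1.21 (camera p = 1.36e-08, and p = 0.00866 with an estimated correlation). Klrg1 (3.26 ± 0.17), Lilrb4a (2.72 ± 0.25), Havcr2, which encodes TIM-3 (2.50 ± 0.16), Ctla4 (1.82 ± 0.17), Pdcd1, which encodes PD-1 (1.24 ± 0.13), and Lag3 (1.16 ± 0.17) were among them, beside the PD-1 ligand gene Pdcd1lg2. The effect differed between genotypes for 8 of the 12. Ctla4 stands also in the T cell list and Klrg1, Cd160 and Cd244a in that of cytotoxic cells, so more lymphocytes in the fat may give the same rise, and levels per cell were not measured.

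Genes of osteoclasts and of fused macrophages rose in 10 of 18 cases and fell in 2, or 11 and 2 adjusted over the list alone (camera p = 0.00026, and p = 0.0302 with an estimated correlation). Ocstamp (3.63 ± 0.23) and Dcstamp (2.47 ± 0.20), which cells need to fuse, rose, and so did Tcirg1 (1.89 ± 0.12). Acp5 fell by 0.96 ± 0.11 and Cd81, which restrains fusion, by 0.58 ± 0.05. Acp5 is itself a marker of osteoclasts. The general macrophage list rose more (median 1.73, against 0.80 here) and shares Trem2 and Tyrobp, so more macrophages in the fat may give the same rise.

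Imprinted genes were lower as a set, with 14 of 32 down and 4 up, or 16 and 4 adjusted over the list alone (median -0.36, camera p = 0.00246, but p = 0.0654 with an estimated correlation). Igf2 (-1.96 ± 0.17), Plagl1 (-1.75 ± 0.27), Zim1 (-1.44 ± 0.13) and Ndn (-1.24 ± 0.13) fell, besides Nnat, Mest and Peg3, which were left out of the list. Gatm, an enzyme of creatine synthesis (2.95 ± 0.16), Asb4 (1.78 ± 0.15), Ascl2 (0.75 ± 0.21) and Igf2r (0.25 ± 0.08) rose. The knockout median was 0.02. The adipocyte (-1.33), endothelial (-1.52) and fibroblast (-0.83) lists had lower medians in the same arrays, so a smaller share of these cells may give the same fall. That imprinted genes fall together is a hypothesis that the estimated correlation leaves undecided.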
